A study of Mus musculus with 12 samples.

How the data were processed

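RNA was measured by sequencing in 12 samples of RAW264.7 cells, a mouse macrophage-like cell line. The labels cross 2 plasmids with 2 infection states: a control (NC) plasmid or miR-26a overexpression, and no infection or 5 h with Listeria monocytogenes (L.m). Each of the 4 groups has 3 samples. The sample titles call the control-plasmid samples WT, while their source names call them NC-plasmid-transfected; the source names were followed. The labels do not say whether the 3 samples of a group were separate cultures or transfections, so the p-values measure the spread between these samples.

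The deposited values are FPKM, as computed by the authors: reads scaled to gene length and library size, with no recorded scaling between samples. The labels name bcl2fastq 2.0, HISAT2, StringTie, DESeq2 and limma and the genome build mm10, without their roles or order. The protocol text describes both a small-RNA size selection with 50-base single-end reads and Illumina library preparation, so how the libraries were made is not settled by the labels. Each file lists 22488 genes, of which 811 carry no Entrez identifier; 26 symbols had been turned into dates by a spreadsheet, and 25 of these were named again through their Entrez identifiers.

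Low FPKM values fell on multiples of a step per gene. With exon lengths from the GENCODE M21 annotation, these steps gave back totals of 3.69 to 7.88 M reads per library, and 98.2% to 98.7% of the low values checked were whole reads within 0.1. This check used values under 15 reads and took the commonest lowest step as 1 read pair. The recovered reads served to state depth and for alternative fits only. Depth in reads is therefore inferred, not given by the authors.

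The main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(FPKM + 1), with genes kept at an FPKM of at least 1 in at least 3 of the 12 samples, which left 10116 genes. One fit held the 4 group means. The contrasts were infection in control-plasmid cells, infection in miR-26a cells, the miR-26a effect without and with infection, and the interaction, which is the infection response in miR-26a cells minus that in control cells. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. The pipeline was tested on simulated data, with normal noise of each gene's fitted spread around the control means: at a log2 change of 1 it recovered 92% to 98% of the genes in the 4 simple contrasts and 80% in the interaction, and it called at most 0.12% of the genes left unchanged. Noise that is not normal or is shared between genes was not simulated.

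Before the data were examined, the tests, the alternatives, 39 gene lists and the rule for naming genes were fixed. The rule named, per contrast, the 6 largest rises and 6 largest falls among called genes whose compared groups did not overlap (for the interaction, among all called genes), leaving out predicted genes, pseudogenes and noncoding RNA genes. It also named reported miR-26a targets and host genes (Epha2, Ezh2, Smad1, Ctdspl and Ctdsp2 here) in every contrast, and up to 4 members of smallest p from each described list. Some genes that the rule picks are not reported here; the counts include them. The level of miR-26a itself was not analysed here. The 32 lists with at least 3 tested members were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over all 160 list tests, and again with an estimated correlation. Counts adjusted over the list alone accompany those over all genes.

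Sites for the miR-26a-5p seed were sought in the longest annotated 3' UTR (at least 50 bases) of each gene: the 8mer TACTTGAA, the 7mer-m8 match TACTTGA and the 6mer match ACTTGA. Of the tested genes, 9927 had such a UTR, and 488 of them held an 8mer. The mean change of these genes was compared with that of the other genes with camera, with 10000 sets matched on 3' UTR length and expression, and with 371 control 8mers made of the same bases in another order. Coordinates are GRCm38 (mm10).

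The analysis was repeated with pseudocounts of 0.1 and 0.01, no filter, an FPKM minimum of 5, median-ratio, quantile and TPM scaling, no variance trend, array weights, fits of only the groups compared, a replicate block, a log2 change of at least 1, and leaving out each library, all chosen before the data were examined. After the data were seen, 3 more were added: leaving out a pair of uninfected miR-26a libraries with raised signal at silent genes, that signal as a covariate, and voom on the recovered reads. A list of 28 hepatocyte genes was also written after the data were seen. Figures were drawn with Matplotlib 3.10.9, and tables were made with pandas 2.3.3 on Python 3.11.15.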

Results

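Transcript levels were measured by RNA sequencing in RAW264.7 cells, a mouse macrophage-like line, that carried a control plasmid or overexpressed miR-26a and were left uninfected or infected with Listeria monocytogenes for 5 h. The series title names EphA2 as a target of miR-26a in resistance to this intracellular bacterium. Each group held 3 libraries. The inferred depth was 7.83, 6.96 and 6.32 M reads in uninfected control cells and 5.99, 6.0 and 7.14 M in uninfected miR-26a cells. It was 6.02, 7.8 and 5.27 M in infected control cells and 7.88, 5.35 and 3.69 M in infected miR-26a cells. At this depth a transcript near 1 FPKM rests on few reads: Epha2 had 14 to 100 reads per library and Il6 had 0 to 81. Infection separated the libraries along the first principal component (64.6% of the variance) and miR-26a along the next (13.6%). Correlations across genes were 0.983 to 0.991 within groups and 0.914 to 0.98 between groups.

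Transcripts foreign to macrophages were also present. Alb, the liver albumin gene, reached 24.2 to 64.5 FPKM as group means, and its level differed between libraries of 1 group (47.1, 12.1 and 13.5 FPKM in infected miR-26a cells). Olfactory and vomeronasal receptor genes averaged 0.0925 and 0.203 FPKM in uninfected miR-26a libraries 1 and 2 and 0.018 to 0.0435 FPKM in the other 10 libraries.

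**Figure D1:**
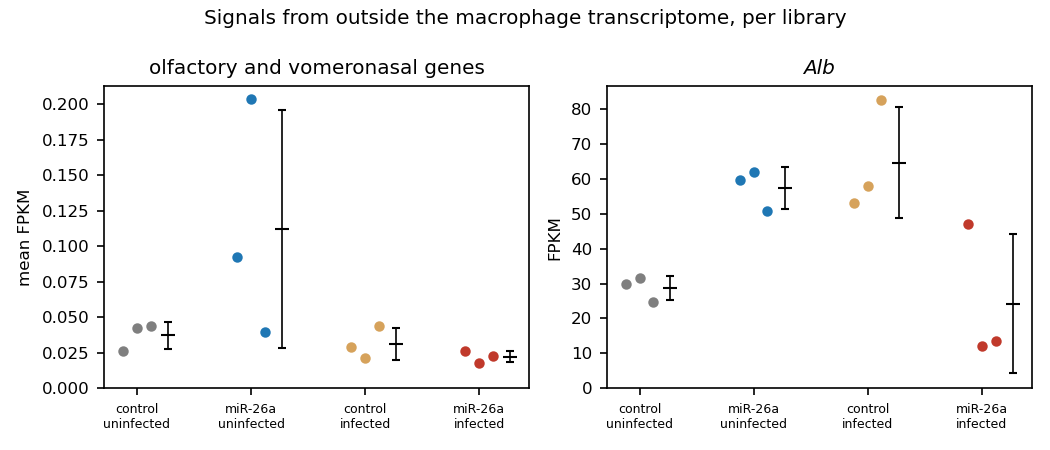
Mean FPKM of 1462 olfactory and vomeronasal receptor genes (left) and FPKM of Alb (right) in each of the 12 libraries by group; dots are libraries, and the dash and bar are the mean and SD of 3. Uninfected miR-26a libraries 1 and 2 stand out on the left at 0.0925 and 0.203 FPKM, and on the right infected miR-26a library 1 lies at 47.1 FPKM and the other libraries of its group at 12.1 and 13.5 FPKM.

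The first comparison asked how control-plasmid cells responded to infection. Chemokines and inflammatory genes rose most. Cxcl2 went from 0.912 ± 0.584 to 224 ± 7.66 FPKM (SD, n = 3), a log2 change of 6.92 (adjusted p 4.66e-13). Ccl3 rose from 61.7 ± 5.48 to 3077 ± 123 FPKM (SD, n = 3) and Ccl4 from 45.5 ± 3.49 to 2230 ± 52.3 FPKM (SD, n = 3). Acod1, which makes itaconate, rose from 7.52 ± 0.905 to 552 ± 1.33 FPKM (SD, n = 3). Ccl2 rose by 5.87 on the log2 scale, and Csf3 by 6.34 from a level of 0.165 FPKM. Tnf reached 860 FPKM from 60.0, Il1b 31.5 from 0.42 and Nos2 17.5 from 0.212. The regulators Il1rn and Nfkbiz reached 237 from 5.05 and 63.3 from 3.3. Among called genes with separate groups, the largest falls included those of Gnat1, Hist1h3a, Fbxo5, Fhod1 and Tcf19. Fbxo5, a regulator of mitotic entry, fell from 39.5 ± 4.84 to 12.4 ± 1.52 FPKM (SD, n = 3; adjusted p 8.39e-09). Gnat1, a gene of photoreceptors, was at 3.92 FPKM in uninfected control cells and under 0.5 FPKM in the means of the other groups. Hist1h3a was listed at 0 in all infected control libraries, and its call was lost without uninfected control library 3 or without infected control library 1, 2 or 3 (adjusted p 0.0616 to 0.127).

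Epha2 (Entrez 13836, chromosome 4, 141301240 to 141329384) fell with infection in control cells, from 2.60 ± 0.123 to 0.737 ± 0.183 FPKM (SD, n = 3), a log2 change of -1.06 (adjusted p 0.000217). Ezh2 (chromosome 6, 47530139 to 47595341) fell from 21.7 ± 1.99 to 12.8 ± 0.305 FPKM (SD, n = 3; adjusted p 6.08e-06). Ctdspl and Ctdsp2 fell by 0.90 and 0.58 on the log2 scale (adjusted p 0.000379 and 0.000578). Smad1 was not called at 0.09 (adjusted p 0.654). In all, 5044 of 10116 genes were called, 1369 higher and 3675 lower. Of these, 431 and 132 changed by at least 1 on the log2(FPKM + 1) scale, which at low FPKM takes more than a 2-fold change. The split into higher and lower genes depends on scaling. The median of all tested genes was -0.18 as deposited and -0.01 after median-ratio scaling, where 2024 genes were higher and 1732 lower. After quantile normalization 1635 were higher and 2646 lower.

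Most tested members of several immune gene lists rose in infected control cells. Of 49 tested interferon-stimulated genes, 47 rose (47 adjusted over the list alone), led by Cmpk2, Rsad2, Ifit2 and Ifit1, with a median log2 change of 1.96 (adjusted p 2.67e-56). All 15 tested pro-inflammatory cytokines rose (15 adjusted over the list alone; median 2.2), with Tnf, Il1b, Csf3 and Lif first. Genes near 0 without infection, such as Csf3 and Il1b, passed the filter through their infected libraries. The filter therefore favors rises of such genes in both infection contrasts. Of 12 chemokines 10 rose and Cxcl14 fell (10 and 1 adjusted over the list alone). NF-kB feedback and anti-inflammatory regulators rose in 26 of 30 cases (26 adjusted over the list alone), among them Il1rn, Nfkbiz, Zfp36 and Dusp5. Immediate early genes led by Atf3, Ier3, Egr1 and Junb rose in 19 of 24 and fell in 3 (19 and 3 adjusted over the list alone). Antigen presentation genes rose in 16 of 20 (17 adjusted over the list alone), with Cd274, Cd40, Tap1 and Nlrc5 first. Antimicrobial effectors split into 8 higher, led by Acod1 and Nos2, and 5 lower (10 and 5 adjusted over the list alone).

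Cell-cycle genes went the other way in infected control cells. All 30 mitotic genes fell (30 adjusted over the list alone), led by Mki67, Ccna2, Top2a and Anln, with a median of -0.73 (adjusted p 1.23e-11). Of 32 DNA replication genes 30 fell (32 adjusted over the list alone), led by Mcm5, Rrm2, E2f8 and Uhrf1, with a median of -0.78. Both medians lay well below the median of all genes, -0.18.

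Further lists passed upward in infected control cells with smaller medians. Higher and lower members were 10 and 1 of 16 for inflammasome genes (Nlrp3, Casp4; 10 and 1 adjusted over the list alone), and 15 and 6 of 26 for pattern recognition (Tlr3, Clec4e; 15 and 7 adjusted over the list alone). They were 11 and 2 of 18 for phagocytosis receptors (Fcgr1, Msr1; 11 and 3 adjusted over the list alone), and 9 and 4 of 19 for NRF2 targets (Sqstm1, Slc7a11; 9 and 4 adjusted over the list alone). Stress genes such as Ppp1r15a and Atf4 gave 11 and 5 of 20 (11 and 5 adjusted over the list alone). Lysosomal genes such as Ctsb gave 14 and 4 of 28, and genes of glycolysis and hypoxia (the glycolytic list) such as Slc2a1 gave 10 and 8 of 24. Listeria entry and actin genes such as Itga5 and Zyx gave 8 and 3 of 24. Each count of the lysosomal, glycolytic and Listeria entry lists was equal when adjusted over the list alone. Of 3 dendritic cell markers Ccl22 and Xcr1 rose (2 adjusted over the list alone). With an estimated correlation the lysosomal (adjusted p 0.0969), glycolytic (0.0716), Listeria entry (0.209) and dendritic (0.109) lists no longer passed. After quantile normalization the NRF2 list missed the threshold too (adjusted p 0.0647). Reported miR-26a targets did not move as a list (9 higher, 11 lower of 35; 9 and 11 adjusted over the list alone; adjusted p 0.37), and its 4 members of smallest p were Pim1, Hmga2 and Slc7a11, which rose, and Ccne2, which fell. Of the Eph receptors and ephrins, Epha2 and Efnb1 were tested and Epha2 alone was called.

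The same infection was then compared in miR-26a cells. Cxcl2, Csf3, Acod1, Ccl2, Ccl4 and Ccl3 were again the 6 largest rises. Acod1 went from 9.46 ± 1.96 to 630.5 ± 11.7 FPKM (SD, n = 3) and Ccl3 from 73.2 ± 6.83 to 3750 ± 235 FPKM (SD, n = 3). The largest falls were those of the histone genes Hist1h2ag, Hist1h2ap and Hist1h3g and of Fabp1, Htr1b and Hpgd. Htr1b, a serotonin receptor gene, fell from 22.6 ± 0.273 to 6.81 ± 0.901 FPKM (SD, n = 3; adjusted p 3.88e-09). Hpgd, which degrades prostaglandins, fell from 7.12 ± 1.13 to 1.78 ± 0.291 FPKM (SD, n = 3; lost at a pseudocount of 0.01, adjusted p 0.162). The Hist1h3g call was lost without uninfected miR-26a libraries 1 and 2. Fabp1 is a liver transcript. Epha2 was not called here, at 1.20 ± 0.357 and 0.967 ± 0.368 FPKM (SD, n = 3; log2 change -0.16, adjusted p 0.463). Ezh2 and Ctdsp2 fell by 0.87 and 0.71 on the log2 scale (adjusted p 9.66e-07 and 0.00012), and Smad1 and Ctdspl were not called.

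In total 4683 genes were called in infected miR-26a cells, 1316 higher and 3367 lower. Of these, 404 and 117 changed by at least 1 on the log2 scale. The split again depended on scaling. After median-ratio scaling 1997 were higher and 1528 lower, and after quantile normalization 1568 and 2518. Without uninfected miR-26a libraries 1 and 2 the count was 2840. The 49 interferon-stimulated genes all rose (49 adjusted over the list alone; median 2.52), led by Cmpk2, Usp18, Rsad2 and Ifit1. Cytokines rose in 14 of 15 (15 adjusted over the list alone), and chemokines in 11 of 12 with Cxcl14 lower (11 and 1 adjusted over the list alone). NF-kB feedback and anti-inflammatory regulators rose in 28 of 30 (28 adjusted over the list alone). All 30 mitotic genes fell (30 adjusted over the list alone), as did 30 of 32 replication genes (31 adjusted over the list alone). Antigen presentation (18 of 20 higher, 18 adjusted over the list alone), immediate early (18 higher and 3 lower of 24), inflammasome (11 and 1 of 16), pattern recognition (17 and 4 of 26) and phagocytosis genes (11 and 2 of 18) also passed upward, with these counts unchanged when adjusted over the list alone. So did NRF2 (10 and 3 of 19, 10 and 3 adjusted over the list alone) and lysosomal genes (15 and 3 of 28, 16 and 3 adjusted over the list alone). Genes of glycolysis and hypoxia passed upward too (11 and 3 of 24, 12 and 3 adjusted over the list alone). Antimicrobial effectors (7 and 4 of 18, 7 and 4 adjusted over the list alone), Listeria entry genes (9 and 3 of 24, 9 and 3 adjusted over the list alone) and dendritic markers (2 of 3, 2 adjusted over the list alone) passed with the preset correlation only, at adjusted p 0.0617, 0.214 and 0.0716 with an estimated correlation. The Listeria entry list had a median of -0.02 and a mean of 0.16, and its median was 0.15 after median-ratio scaling and 0.00 after quantile normalization, where the call was lost (adjusted p 0.0904). Oxidative phosphorylation genes, led by Atp5o, Atp5c1, Uqcrc2 and Cox5a, fell in 19 of 32 (20 adjusted over the list alone), a call lost with an estimated correlation (adjusted p 0.463) or median-ratio scaling (0.197). Reported miR-26a targets gave 9 higher and 12 lower of 35 (10 and 12 adjusted over the list alone; adjusted p 0.364).

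The infection responses of the 2 cell populations share no library. Of the called genes, 1084 rose in both (178 by independent calls), 2585 fell in both (1223 by independent calls) and 26 went opposite ways. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.875 and a Spearman correlation of 0.756.

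The effect of miR-26a in uninfected cells, meaning miR-26a against control-plasmid cells, addressed its targets. In every such comparison here, differences between the transfected populations that do not come from miR-26a cannot be told apart from its effect. Epha2, whose 866-base 3' UTR holds one 8mer site, was lower in miR-26a cells, at 1.20 ± 0.357 against 2.60 ± 0.123 FPKM (SD, n = 3), a log2 difference of -0.72 (adjusted p 0.0139). The libraries of the 2 groups did not overlap, which chance gives in 10% of comparisons for one gene. This call was lost without uninfected control library 1 (adjusted p 0.0566) and without uninfected miR-26a library 1 (0.067). In these fits the log2 difference was -0.698 to -0.582. The call was also lost without miR-26a libraries 1 and 2 together, with their background as a covariate (adjusted p 0.164) and at a pseudocount of 0.01 (0.0538). Ezh2, with an 8mer in its 402-base 3' UTR, was not called at 22.9 ± 1.5 against 21.7 ± 1.99 FPKM (SD, n = 3; adjusted p 0.604). Smad1 (chromosome 8, 79338395 to 79399518) was higher in miR-26a cells, at 2.15 ± 0.292 against 0.326 ± 0.0278 FPKM (SD, n = 3; adjusted p 5.29e-05), and its 3' UTR held no seed match. Ctdspl (chromosome 9, 118926453 to 119043998), a host gene of a miR-26a precursor, was lower at 0.33 ± 0.0448 against 1.98 ± 0.172 FPKM (SD, n = 3; adjusted p 0.000194). Ctdsp2 was not called (adjusted p 0.924). The uninfected control libraries, the reference here, also held the photoreceptor gene Gnat1, at 3.41, 4.17 and 4.18 FPKM. Gnat1 was at most 0.555 FPKM in any other library. Whether foreign RNA bears on the levels of Epha2 or Ctdspl in these reference libraries was not tested.

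**Figure D2:**
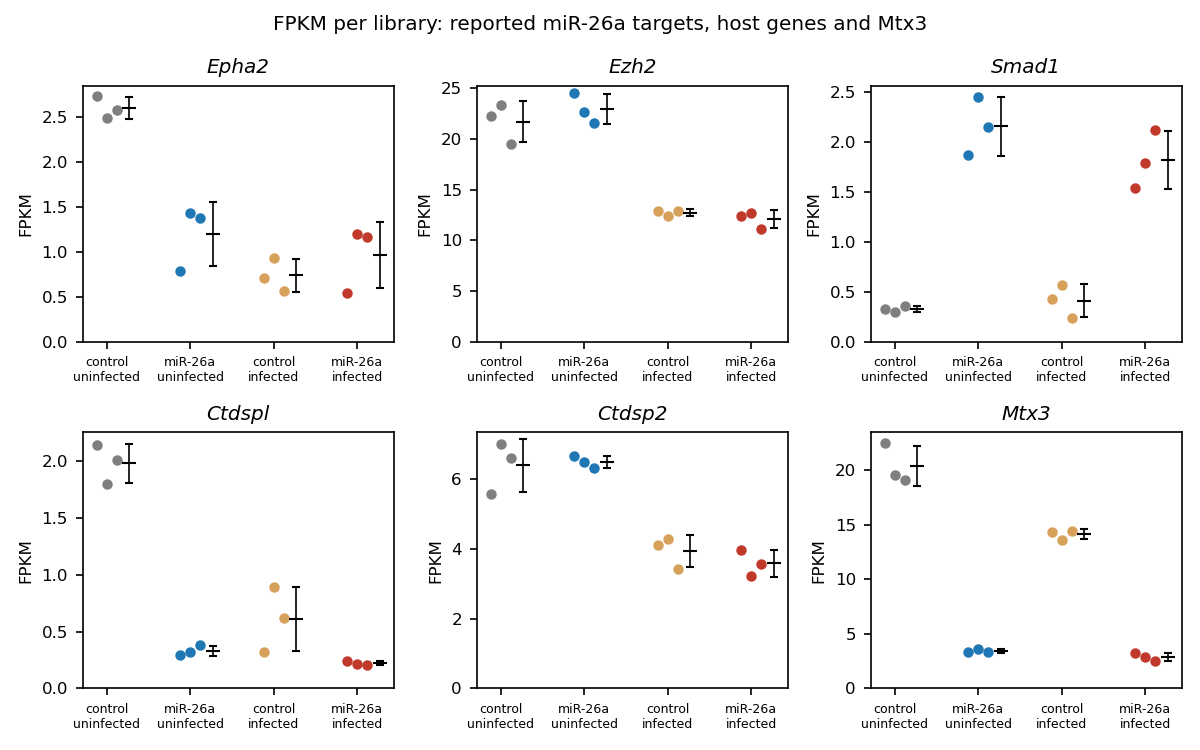
FPKM of Epha2, Ezh2, Smad1, Ctdspl, Ctdsp2 and Mtx3 in each of the 12 libraries by group; dots are libraries, and the dash and bar are the mean and SD of 3. Epha2 stood at 2.60 FPKM in uninfected control cells and between 0.737 and 1.20 FPKM in the means of the other groups, while Mtx3 was low in both miR-26a groups.

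Genes with miR-26a seed sites did not move as a set in uninfected cells. The 488 genes with an 8mer averaged 0.01 against 0.00 for the other genes with a 3' UTR, and 33 of them (6.8%) were lower against 7.4% of the others. Camera gave p 0.489, and sets matched on UTR length and expression gave p 0.81. Of 371 control 8mers, 49 gave a difference as low or lower, and their median was 0.03. In infected cells 43 of the 488 genes (8.8%) were lower against 8.7% of the others (camera p 0.331, matched sets p 0.716), and 107 of the 371 control 8mers gave a difference as low or lower, with a median of 0.04. Of the 35 reported miR-26a targets, 5 were higher without infection, namely Slc7a11, Plod2, Smad1, Hmga2 and Ccnd2, and 3 were lower, among them Cdk6 and Epha2 (6 and 3 adjusted over the list alone; adjusted p of the list 0.29). Ccnd2 and Cdk6 were chosen after their values were seen, to complete these counts.

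Beyond reported targets, Basp1, Spink5, Rhox5, Pdgfa, Cxcl14 and Gpnmb were the largest rises in uninfected miR-26a cells. Spink5 (chromosome 18, 43963235 to 44022501), a protease inhibitor gene, stood at 143 ± 1.68 against 18.5 ± 0.527 FPKM (SD, n = 3; adjusted p 6.35e-13). Basp1 stood at 14.8 ± 1.01 against 0.925 ± 0.265 FPKM (SD, n = 3). Mtx3, Irf7, Ifi27l2a, Ltb and Runx3 were among the largest falls. Mtx3 (chromosome 13, 92844760 to 92858230), a mitochondrial outer membrane gene with a 7mer site, was at 3.43 ± 0.15 against 20.3 ± 1.84 FPKM (SD, n = 3; log2 difference -2.27, adjusted p 8.01e-10). Irf7 (chromosome 7, 141262706 to 141266481), an interferon regulator, was at 13.7 ± 0.488 against 57.7 ± 5.38 FPKM (SD, n = 3; adjusted p 1.31e-10), with no seed match in its 3' UTR. The lymphocyte-related genes Ltb and Runx3 were at 3.6 and 3.09 FPKM against 16.2 and 13.7 FPKM. In all, 1244 genes were called, 508 higher and 736 lower, with 59 and 73 at 1 or more on the log2 scale. The count was 820 without uninfected control library 1 and 460 without both uninfected miR-26a libraries 1 and 2.

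Interferon-stimulated genes were lower in uninfected miR-26a cells. Of 49 tested, 41 were lower and none higher (45 lower adjusted over the list alone), led by Irf7, Oasl2, Ifi44 and Irgm1, with a median of -0.99 (adjusted p 2.45e-58, and 2.07e-05 with an estimated correlation). Antigen presentation genes were lower in 11 of 20 (11 adjusted over the list alone; H2-T23, Cd74, Psmb10, Tap1; median -0.41). Cholesterol synthesis genes were lower in 7 of 21 (7 adjusted over the list alone; adjusted p 0.00053). Osteoclast genes were higher in 5 of 10 (6 higher and 1 lower adjusted over the list alone; Nfatc1, Car2, Mmp9, Atp6v0d2; median 0.58), and the Atp6v0d2 call was lost without miR-26a libraries 1 and 2 together (adjusted p 0.0994). Genes of p53 were lower in 5 and higher in 1 of 15 (8 and 2 adjusted over the list alone), led by Cdkn1a and Phlda3, with adjusted p 0.0548 with an estimated correlation. Lyz2 led the antimicrobial effectors at 6613 ± 175 against 3287 ± 72.2 FPKM (SD, n = 3), with 5 higher and 2 lower of 18 (9 and 3 adjusted over the list alone). The antimicrobial (0.135), inflammasome (4 lower and 1 higher of 16, 7 and 1 adjusted over the list alone; 0.0716), glycolysis (6 lower and 2 higher of 24, 7 and 2 adjusted over the list alone; 0.0875) and mitosis lists (3 higher of 30, 2 adjusted over the list alone; 0.115) passed with the preset correlation only, the adjusted p with an estimated correlation being given here. The glycolysis call was also lost without uninfected control library 2 (0.0557) or miR-26a libraries 1 and 2 together (0.076), and the mitosis call without uninfected control library 1 or 3 or miR-26a library 1 or 3 (0.0504 to 0.0937). The mitotic genes called were Aurkb, Top2a and Prc1; Top2a was lost without uninfected control library 1 or uninfected miR-26a library 1 or 3 (0.0662 to 0.0932), and Prc1 without any of the 6 uninfected libraries or infected control library 2 (0.0519 to 0.177). Without miR-26a libraries 1 and 2 together both were lost (0.117 and 0.338), as was mt-Cytb (0.346). Mitochondrially encoded genes were higher in 8 of 13 (8 adjusted over the list alone), but mt-Nd5 and mt-Cytb turned lower after quantile normalization and the list missed the threshold with an estimated correlation (adjusted p 0.142). Cytokines gave 1 lower gene of 15, Tnfsf9 (1 adjusted over the list alone), and chemokines gave Cxcl14, Ccl5 and Ccl22 higher and Cxcl10 lower of 12 (4 and 1 adjusted over the list alone). The Ccl22 call was lost without any uninfected control library or uninfected miR-26a library 1 or 2 (adjusted p 0.0542 to 0.128), or without both of these (0.431).

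**Figure D3:**
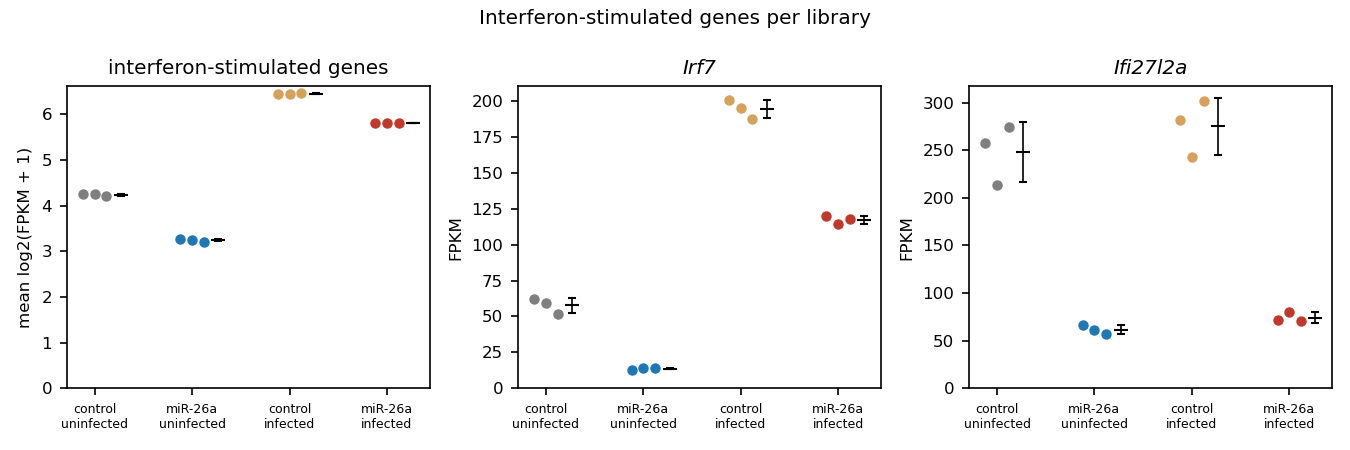
Mean log2(FPKM + 1) of the interferon-stimulated genes (left) and FPKM of Irf7 and Ifi27l2a in each of the 12 libraries by group; dots are libraries, and the dash and bar are the mean and SD of 3. The list averaged 4.24 in uninfected control cells and 3.24 in uninfected miR-26a cells, and 6.46 and 5.8 after infection.

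The effect of miR-26a was also measured in infected cells. Spink5, Cxcl14, Gpnmb, Serinc2, Mmp9 and Basp1 were the largest rises. Spink5 stood at 239 ± 5.31 against 30.0 ± 2.5 FPKM (SD, n = 3) and Mmp9 at 11.6 ± 1.79 against 1.43 ± 0.303 FPKM (SD, n = 3). Ighj1, Fabp1, Hsh2d, Il27, Mtx3 and Ifnb1 were the largest falls. Ifnb1, the interferon beta gene, reached 3.83 ± 0.495 against 16.8 ± 0.699 FPKM (SD, n = 3; adjusted p 0.000648), from 10 to 26 reads per miR-26a library. Il27 reached 8.60 ± 2.54 against 37.8 ± 2.83 FPKM (SD, n = 3; adjusted p 1.73e-05). Il6 reached 0.788 ± 0.963 against 4.70 ± 0.547 FPKM (SD, n = 3; adjusted p 0.00043). In contrast Il1a was higher at 22.0 ± 2.53 against 4.06 ± 0.818 FPKM (SD, n = 3; adjusted p 7.11e-07), and Lif was higher at 18.6 ± 1.19 against 6.78 ± 0.287 FPKM (SD, n = 3; adjusted p 9.37e-07). Epha2 was not called in infected cells, at 0.967 ± 0.368 against 0.737 ± 0.183 FPKM (SD, n = 3; log2 difference 0.17, adjusted p 0.572). Ezh2, Ctdspl and Ctdsp2 were not called either (adjusted p 0.596, 0.126 and 0.55), and Smad1 was higher (adjusted p 0.000388). With no variance trend Ctdspl was called lower (-0.38, adjusted p 0.0367). The calls of Il6 and Il1a, which lay near 0 without infection, were lost at a pseudocount of 0.01 (adjusted p 0.159 and 0.118), where the log2 differences were -3.33 and 2.45 against -1.80 and 2.19. The Ighj1 call rested on 0 to 7 reads per infected library and was lost without infected control library 2 or infected miR-26a library 1 or 3 (adjusted p 0.0518 to 0.0688).

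**Figure D4:**
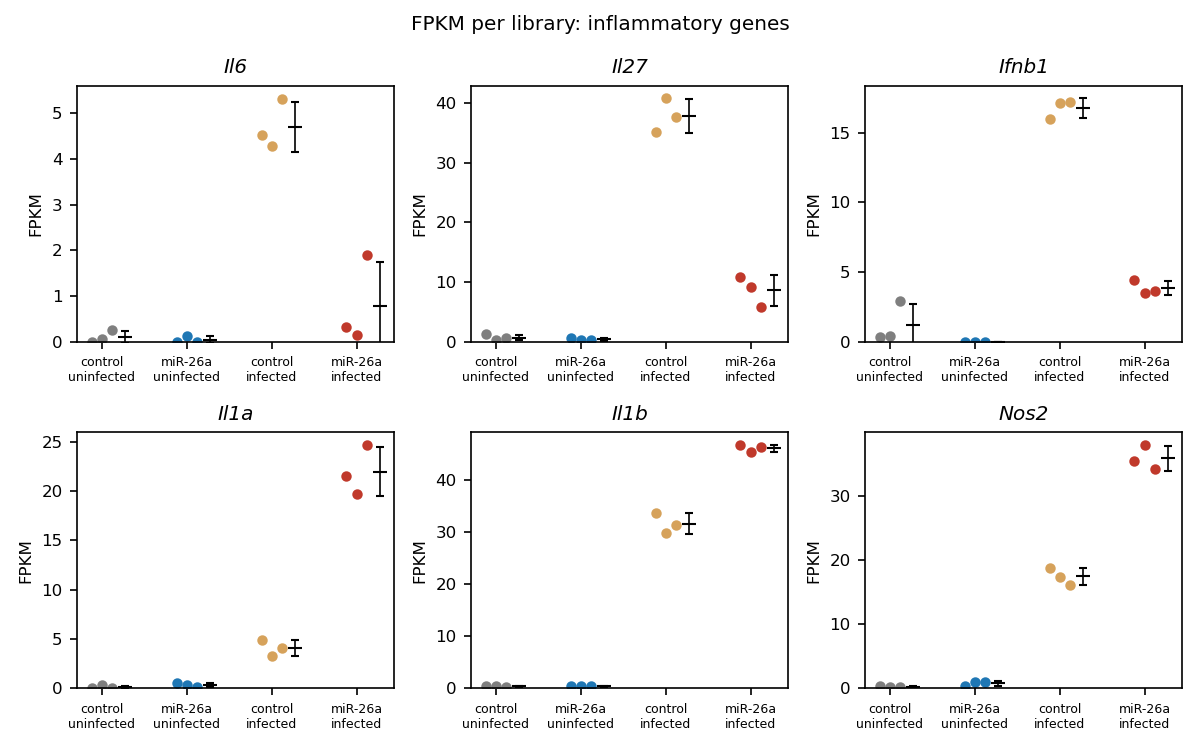
FPKM of Il6, Il27, Ifnb1, Il1a, Il1b and Nos2 in each of the 12 libraries by group; dots are libraries, and the dash and bar are the mean and SD of 3. After infection Il6, Il27 and Ifnb1 were lower in miR-26a cells than in control cells, and Il1a, Il1b and Nos2 were higher.

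Interferon-stimulated genes remained lower in infected miR-26a cells, with 44 of 49 lower (46 adjusted over the list alone), led by Ifi27l2a, Oasl2, Irf1 and Cmpk2, and a median of -0.64 (adjusted p 4.31e-35). Antigen presentation genes were lower in 12 and higher in 1 of 20 (12 and 1 adjusted over the list alone; H2-T23, Cd74, Tap1, Psmb8). Osteoclast genes were higher in 6 of 10 (7 higher and 2 lower adjusted over the list alone; Mmp9, Nfatc1, Car2, Atp6v0d2). NRF2 targets were higher in 9 and lower in 2 of 19 (10 and 2 adjusted over the list alone; Slc7a11, Gclc, Srxn1, Mt1). Cytokines split into 3 higher and 5 lower of 15 (3 and 6 adjusted over the list alone), and chemokines into 4 higher and 1 lower of 12 (4 and 1 adjusted over the list alone), Cxcl10 being the lower one. Antimicrobial effectors gave 6 higher and 3 lower of 18 (6 and 4 adjusted over the list alone), with Lyz2 again first at 5247 against 2607 FPKM. Reported miR-26a targets gave 9 higher and 4 lower of 35 (9 and 7 adjusted over the list alone; adjusted p 0.541), led by Plod2, Slc7a11, Smad1 and Il6. The p53 (2 higher, 5 lower of 15; 2 and 7 adjusted over the list alone), lysosome (11 and 3 of 28; 12 and 3 adjusted over the list alone) and mitochondrial lists (8 higher of 13; 11 adjusted over the list alone) passed with the preset correlation, at adjusted p 0.13, 0.228 and 0.145 with an estimated correlation. Within the last list mt-Cytb turned lower after quantile normalization (-0.22). The cytosolic ribosomal protein list passed downward with a median of -0.10, a call lost without infected miR-26a library 3 (0.16) and with an estimated correlation (0.586). Its called members were Rpl6 and Rpl11 (none adjusted over the list alone): Rpl6 was lost without any library but uninfected miR-26a library 1 (0.0539 to 0.15) and without uninfected miR-26a libraries 1 and 2 together (0.0513), and Rpl11 without any but uninfected or infected miR-26a library 1 (0.0528 to 0.169). In all, 1716 genes were called, 833 higher and 883 lower, with 59 and 71 at 1 or more on the log2 scale. The 2 effects of miR-26a share no library: 313 genes were higher in both (41.8 by independent calls), 424 lower in both (64.2) and 12 opposite, with a Pearson correlation of 0.539 and a Spearman correlation of 0.498 across genes.

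The interaction asked whether the response to infection differed between miR-26a and control cells. On the log2 scale, interferon-stimulated genes rose more in miR-26a cells, from their lower start. Irf7, Ifi44, Ifi44l and Trim30a had interactions of 1.27, 1.20, 1.42 and 0.86 (adjusted p 7.78e-06, 7.78e-06, 1.37e-05 and 3.41e-05). After infection the list still averaged 5.80 in miR-26a cells against 6.46 in control cells, in log2(FPKM + 1). Tnfrsf1b, a TNF receptor gene, reached 87.6 ± 4.19 FPKM in infected miR-26a cells against 43.2 ± 2.25 FPKM in infected control cells (SD, n = 3; interaction 1.48, adjusted p 3.41e-05). Il1a, Lif and Ccl9 rose more in miR-26a cells (1.91, 1.17 and 0.70) and Il27 and Ccl5 rose less (-1.80 and -1.15). For Il1a and Lif, which started near 0, the interaction depended on the pseudocount: at 0.01 that of Il1a was -0.83 (adjusted p 0.885) and that of Lif 0.50 (0.545). Both were also lost at 0.1 (0.566 and 0.195) and with voom (0.944 and 0.848), and that of Il1a on the TPM scale (0.0676). Epha2 had an interaction of 0.89 that missed the threshold (adjusted p 0.107; 0.0357 without infected miR-26a library 1). Ezh2, Smad1, Ctdspl and Ctdsp2 were not called (adjusted p 0.129 to 0.806), though Ctdspl was with no variance trend (0.78, adjusted p 0.0376).

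Transcripts foreign to these cells were among the other large interactions. Fabp1, Ttr, Alb, Rbp4, Serpina3k and Hpx, all made by hepatocytes, were the 6 largest falls, and the photoreceptor gene Gnat1 was among the 6 largest rises. The Gnat1 call was lost at pseudocounts of 0.1 and 0.01 (adjusted p 0.461 and 0.995), on the TPM scale (0.0908), with voom (0.766) and without uninfected miR-26a libraries 1 and 2 (0.0755). Serpina3k was lost without any library but infected miR-26a library 1 (adjusted p 0.0623 to 0.109), Ttr without any but infected miR-26a libraries 1 and 2 (0.0638 to 0.107), and Rbp4 without uninfected miR-26a library 2 (0.0507). Hpx was lost without any but uninfected control library 1, uninfected miR-26a library 3, infected control library 2 and infected miR-26a libraries 1 and 2 (0.0526 to 0.0667). Of 27 tested hepatocyte genes, 15 were called with a negative interaction and 0 with a positive one. The values of all 27 were negative, from -2.969 to -0.893. In all, 180 genes had an interaction, 108 positive and 72 negative, with 12 and 37 at 1 or more on the log2 scale. The count was 107 without uninfected control library 1, 118 without uninfected control library 2, 117 without infected control library 1, 116 without infected control library 3, and 57 (49 positive) without uninfected miR-26a libraries 1 and 2. All 6 liver genes named here were among those lost without these 2 libraries (adjusted p 0.083 to 0.337), as were Gnat1, Il6, Il27, Il1b, Cxcl10, Cxcl14, Mt1, Ncf4, Ndrg1, Sdf2l1, Hspa5 and Ctsc (0.0509 to 0.281).

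The calls of several interactions were lost when a single library was left out, though the values kept their sign. In the fits that lost the call, Il6 ranged from -1.816 to -1.466, Il1b from 0.519 to 0.584 and Cxcl14 from 0.42 to 0.465. Hspa5 ranged from -0.27 to -0.247 and Ndrg1 from 0.539 to 0.624. Il6 (-1.72) was lost without any library but infected miR-26a library 3 (adjusted p 0.0592 to 0.104). Il1b (0.57) was lost without any but uninfected control library 3, uninfected miR-26a library 3 and infected control library 1 (0.0582 to 0.0876). Cxcl14 (0.47) was lost without uninfected control library 1 or 3, uninfected miR-26a library 2 or 3, or infected control library 1 or 2 (0.0551 to 0.0756). Hspa5 (-0.26) was lost without any but uninfected miR-26a library 2, infected control library 1 and infected miR-26a libraries 1 and 3 (0.0553 to 0.099). Ndrg1 (0.61) was lost without any but uninfected control library 2, uninfected miR-26a libraries 2 and 3 and infected miR-26a library 1 (0.0512 to 0.0658).

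As lists, interferon-stimulated genes had 22 positive interactions and 1 negative of 49 (31 and 5 adjusted over the list alone; median 0.39, adjusted p 6.98e-24). NRF2 targets gave 2 positive of 19, Mt2 and Mt1 (5 adjusted over the list alone), and stress genes 2 negative of 20, Sdf2l1 and Hspa5 (3 adjusted over the list alone). Glycolysis and hypoxia genes gave 1 positive of 24, Ndrg1 (3 adjusted over the list alone). These 4 lists also passed with an estimated correlation. Cholesterol synthesis (0 of 21 called, 0 adjusted over the list alone), oxidative phosphorylation (0 of 32, 0 adjusted over the list alone) and lysosome genes (Ctsc negative of 28; 1 negative and 1 positive adjusted over the list alone) did not, at adjusted p 0.0716, 0.564 and 0.162. The Ctsc call was lost without uninfected miR-26a libraries 1 and 2 (adjusted p 0.0798). The oxidative phosphorylation call was also lost without uninfected control library 2 or 3, uninfected miR-26a library 1, infected control library 1 or 3 or infected miR-26a library 3 (adjusted p 0.0562 to 0.331), and without both uninfected miR-26a libraries 1 and 2 (0.12). Cytokines gave 3 positive and 2 negative of 15 (3 and 4 adjusted over the list alone), chemokines 2 and 2 of 12 (3 and 2 adjusted over the list alone), antimicrobial effectors Ncf4 positive and the liver transcript Hp negative of 18 (1 and 1 adjusted over the list alone), and reported miR-26a targets Il6 alone of 35 (1 adjusted over the list alone). The Hp call was lost with the silent-gene background as a covariate (-1.51, adjusted p 0.0932).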

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

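The 3 tests of the silent-gene signal, the test of liver regulation and the share of interferon genes with a site were chosen only after the results they bear on had been seen.

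The test of the difference between the infection responses marked 180 genes as responding differently in miR-26a and control cells. Without uninfected control library 1 it marked 107. The same contrast marked the lists of interferon-stimulated genes (median 0.391), NRF2 targets (0.104), stress response (-0.154), and glycolysis and hypoxia (0.112). It also marked cholesterol synthesis (0.101), oxidative phosphorylation (-0.089) and lysosome genes (0.109), but these did not pass with an estimated correlation. The oxidative phosphorylation call was also lost in 6 of the fits that left out a single library. Against regrouped samples, 2 of 100 splits reached 180 (the real one included), the highest other giving 2434. That split exchanged plasmid labels within an infection state, so it measures the effect of the plasmid. Splits that mix the plasmids put the plasmid effect into the residual spread, which lowers their counts. The share of splits therefore cannot weigh chance for the interaction.

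Named genes with a difference were Il1a (1.913), Gnat1 (1.539), Tnfrsf1b (1.478), Ifi44l (1.416), Irf7 (1.273), Ifi44 (1.195) and Trim30a (0.857). Cytokine and chemokine genes were Lif (1.17), Il27 (-1.803), Il6 (-1.719), Il1b (0.573), Ccl9 (0.703), Ccl5 (-1.148), Cxcl10 (-0.476) and Cxcl14 (0.467). Liver genes were Fabp1 (-2.969), Ttr (-2.804), Alb (-2.601), Rbp4 (-2.49), Serpina3k (-2.206), Hpx (-2.191) and Hp (-1.718). The others were Mt2 (1.213), Mt1 (0.553), Ncf4 (0.463), Ndrg1 (0.609), Sdf2l1 (-0.706), Hspa5 (-0.262) and Ctsc (-0.67).

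Alb and other liver genes moved together between libraries. Read pairs of 27 hepatocyte genes stayed close to 1 profile, with a deviance of 1.34 per degree of freedom, as RNA of a single liver source in varying amounts would give. The value was 85.2 for 48 interferon-stimulated genes, but these values cannot be compared directly, since deviance grows with read number. Rsad2 had 175 to 18584 reads per library and Ttr 0 to 52. Fabp1 strayed from the profile, with 6 reads beside 869 of Alb in infected miR-26a library 1 and 30 beside 1019 in infected control library 3. The profile test was written before it was run, but the shared movement had already been seen. Regulation by miR-26a or infection stays open. Summed hepatocyte reads spanned 3.92-fold within the infected miR-26a libraries, but this rests on library 1 (1.29-fold without it), and the spans in the other groups were 1.11, 1.38 and 1.58. Group means were 173 ± 9.22 and 332 ± 53 reads per M in uninfected control and miR-26a cells, and 356 ± 89.6 and 138 ± 107 in infected ones (SD, n = 3). How liver RNA could have reached the libraries also stays open.

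Olfactory and vomeronasal genes were raised in uninfected miR-26a libraries 1 and 2. Keratin-associated, beta-defensin and taste receptor genes, other silent families, were 4.71 times higher there than in the other 10 libraries, which is consistent with reads from genomic DNA. Deeper sequencing is argued against by their read totals, 0.933 times those of the other libraries. An effect of miR-26a on silent genes is argued against by the infected cells, where the miR-26a libraries had 0.71 times the signal of the controls. Intronic or intergenic reads, which would test for DNA directly, were not analysed here.

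Interferon-stimulated genes were lower in miR-26a cells before infection. Scaling is argued against by a median of -0.991 under the scaling nearest 0, and the silent-gene background by a median of -1.04 with that background as a covariate. Seed sites were not commoner among the 41 lowered genes (odds ratio 0.61, interval 0.12 to 1.92), so a contribution of direct targeting stays open. Direct targeting of most of them is argued against, since 7.3% (3 of 41, limits 1.5% to 19.9%) had a 7mer-m8 site or better. A difference between the transfected cell populations that does not come from miR-26a could not be tested with these samples.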

How the results depend on the processing

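No test named in this part was chosen to explain a change; the background settings and voom were chosen only after the data were seen. Over all settings, values for the genes picked by the naming rule kept their call and direction 9186 times, lost it 433 times, gained it 34 times and reversed 4 times; list tests kept it 4134 times, lost it 71 times and gained it 68 times. The tests of seed-site genes kept their result in all 60 cases, though the uninfected difference was -0.0072 with no filter.

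Infection in control cells gave 4323 to 5239 genes, and in miR-26a cells 3974 to 4646, when single libraries were left out. The miR-26a effect gave 820 to 1375 genes without infection and 1270 to 1661 with it, and the interaction 107 to 169. The seed-site difference ranged from 0.0049 to 0.0114 without infection and from 0.02 to 0.0413 with it. Fewer samples lower the power by construction. A log2 change of at least 1, stricter by construction, left 563, 521, 132, 130 and 49 genes (12 positive) in the 5 contrasts. With no filter, 21116 genes were tested and the interaction count was 110; the cause was not tested. Without both uninfected miR-26a libraries 1 and 2, the counts were 2840 (infection in miR-26a cells), 460 (miR-26a without infection) and 57 (interaction); the remaining library was assumed to vary like the other groups. With the background as a covariate they were 2398, 576 and 51; the cause was not tested.

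The Il1a interaction reversed to -0.827 at a pseudocount of 0.01 (adjusted p 0.885). After quantile normalization the miR-26a effect reversed for mt-Nd5 without infection (-0.114) and for mt-Cytb without (-0.188) and with infection (-0.224); the cause was not tested. With replicate numbers as a block, the counts were 4951, 4593, 1127, 1639 and 139, and correlations were -0.035 to 0.059 (median 0.004) for a shared number and -0.077 to 0.073 (median -0.008) otherwise, 6 of 12 samples being best with their own number. Fits of only the groups compared give no interaction. At 3.69 to 7.88 M reads, genes under about 1 FPKM rest on few reads.

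Regrouped samples offered 10 splits per 2-group contrast, too few for a share under 0.05. Real and highest other counts were 5044 and 0, 4683 and 1, 1244 and 0, and 1716 and 1, so 1 split reached the real count each time. Every other split mixes the 2 real groups, which puts the group effect into the residual spread and lowers its count. These counts therefore cannot weigh chance. For seed-site genes the real and highest other values were 0.0085 and 0.01, and 0.0292 and 0.0379, with 2 splits reaching the real value.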

Other observations

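Apart from Ctdspl, Ctdsp2, Hpgd, Fcgr1, Cd14 and Sqstm1, which the naming rule gave in at least 1 contrast, the genes named in this part were chosen after their values were seen. The hepatocyte reads are those of the test of liver regulation, chosen only after its result was seen, on a list written after the data were seen.

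Ptgs2, which makes prostaglandin precursors, rose from 16.3 to 374 FPKM with infection in control cells and from 19.0 to 257 FPKM in miR-26a cells, an interaction of -0.75 (adjusted p 0.000301). Hpgd, which degrades prostaglandins, was higher in uninfected miR-26a cells (log2 difference 1.84, adjusted p 0.00023), and Alox5 and Alox5ap were lower (-0.51 and -0.55). The prostaglandin list did not pass without infection (3 higher, 2 lower of 12; 3 and 2 adjusted over the list alone; adjusted p 0.568). Among lipid genes, Scd2, Scd1 and Pltp were lower in uninfected miR-26a cells (-1.18, -1.21 and -0.95) and Cd36 was higher (1.21), and the list of LXR targets did not pass (2 higher, 5 lower of 11; 4 and 5 adjusted over the list alone; adjusted p 0.269).

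Macrophage genes moved both ways with infection in control cells: Fcgr1 rose from 62.0 to 177 FPKM and Cd14 from 512 to 1018 FPKM, and Cebpa, Cx3cr1 and Csf1r fell (-1.21, -0.86 and -0.58), with 5 higher and 8 lower of 17 (6 and 9 adjusted over the list alone; adjusted p 0.897). The microRNA-processing genes Dgcr8, Xpo5 and Drosha fell (-0.57, -0.46 and -0.44), while the list had 1 higher and 8 lower of 15 (1 and 8 adjusted over the list alone; adjusted p 0.23). Autophagy genes gave 4 higher, Sqstm1 first at 1.90, and 6 lower of 25 (4 and 5 adjusted over the list alone; adjusted p 0.343). The host genes Ctdspl and Ctdsp2 and the related gene Ctdsp1, tested as 1 list, all fell (3 adjusted over the list alone; adjusted p of the list 0.102). Histone genes gave 5 lower of 15 (2 adjusted over the list alone; adjusted p 0.878).

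Of markers of other blood cells, Ighm was lower in miR-26a cells, at 17.8 against 38.9 FPKM without infection and 18.8 against 48.8 FPKM with it (adjusted p 1.87e-06 and 5.38e-07). Lck rose with infection from 1.22 to 4.16 FPKM in control cells and from 1.32 to 3.47 FPKM in miR-26a cells. No epithelial or erythroid marker reached the tested set. Hepatocyte genes took 170.5, 183.2 and 165.3 reads per M in uninfected control libraries and 347.6, 376.1 and 273.5 in uninfected miR-26a libraries. They took 288.9, 321.2 and 457.7 in infected control libraries and 260.8, 66.5 and 85.9 in infected miR-26a libraries.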
